A study of Homo sapiens with 8 samples.

How the data were processed

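Gene expression was measured by RNA sequencing in NKM-1, an established human myeloid leukemia cell line, after 48 h with SF153 at 30 uM or with DMSO, the solvent control. Per the labels' protocols, ribosomal RNA was removed from total RNA by hybridization to DNA oligonucleotides and RNase H digestion, the remaining RNA was fragmented and randomly primed, and dUTP marking of the second strand kept strand information. Total RNA prepared in this way holds nuclear, noncoding and unpolyadenylated RNA beside mature mRNA. The 8 libraries comprised 4 of each treatment, 2 from each of 2 batches that the labels number 1 and 2. Libraries are named by batch and library number, so that SF153 2.1 is the first SF153 library of batch 2. Nothing in the labels says that libraries 1.1 and 1.2 came from separate cultures. Column names of the 2 libraries of a treatment and batch share a leading number and differ by letter and index pair. They may thus be 2 libraries of 1 sample. The p-values measure only the spread between these libraries, which may be technical.

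The deposited values are recorded here as a signal, which the authors' file labels describe as both CPM and TPM. The columns summed to between 828381 and 1027119 over the same 17912 genes, whereas the sum of plain TPM over all genes is fixed and the same in each library. The values are therefore of a TPM type but not plain TPM, and a scaling between libraries that would account for the sums is not given in the sources used here. The analysis plan, fixed before the data were examined, had assumed TPM; the same test was applied to the signal values. CASAVA 1.8.2, STAR, Salmon, edgeR and build GRCh38 are named, per the submitters' processing notes, without their roles, and the authors' gene filter is not given in the sources used here. Each file held 2 libraries of one treatment and batch, with an Ensembl gene identifier, a symbol and a biotype per row. Of the 8 value columns, 4 were spelled slightly differently from the library names in the labels and were matched by their number, letter, index pair and sample number. No read totals could be recovered from values of this kind, so the depth of each library is unknown and no counting interval or detection floor is given. Because a TPM-type value is a share of its library, a fall of very abundant transcripts raises the values of others, and a scaling with one factor per library acts on all genes of that library alike.

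Transcript lengths and gene positions were taken from GENCODE release 29 on GRCh38, which matched 17235 of the 17912 identifiers without their version numbers, and current symbols were matched for 17887. The files use a newer annotation than release 29, so positions are those of the matched gene in release 29. Length means the longest basic transcript of a gene.

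Differences between SF153 and DMSO were tested with limma 3.58.1 in R 4.3.3 on log2(signal + 1), with an intensity trend in the variance prior, for the 15542 genes with a mean signal of at least 1 over all 8 libraries. The fit compared 4 SF153 with 4 DMSO libraries without a batch term. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, with no fold threshold. Fold changes are on the log2(signal + 1) scale, which understates the change of genes with low signal. A set of 35 gene lists was fixed before the data were examined. The 33 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over lists. Camera asks whether a list moved relative to the other tested genes. The tests were repeated with a correlation estimated from each list and with fry, which asks whether a list's own genes moved on balance one way. Counts of called list members refer to adjustment over all genes tested unless they are described as adjusted over the list alone.

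The genes named were chosen by a rule fixed before the data were examined. It took the 10 largest increases and the 10 largest decreases among called genes that lay on the same side in both batches, had a mean signal of at least 5 in one group and had an official symbol. It added up to 4 called members of each list with the largest absolute change, and allowed every member of the UHM list. The histone copy H3C14 and the paralog BOLA2B were named in addition, after their values were seen, because they share sequence with named genes. One gene that the rule selected is not reported here.

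Samples are paired by batch, since the labels' batch number marks a shared batch. The pairing left little trace in the values. Across genes, the batch 1 minus batch 2 difference of DMSO had a Pearson r of 0.067 with that of SF153, and deviations of libraries of the same batch but different treatment from their group means had a mean r of 0.026. Genes are not independent replicates.

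Alternatives covered the pseudocount, the filter on low values, 3 other scalings, the variance model, batch as a block or random effect, averaging of the libraries of one treatment and batch, and each library left out in turn. Fits to each batch alone, a treatment and batch random effect, and removal of the trend on transcript length and mean signal were added after seeing the data, as were the list tests within batches, on averages, after median-of-ratios scaling and after trend removal. The values used here are not counts, so count models were not run.

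The gene test was tested on simulated data for the comparison of SF153 with DMSO, with 200 of 15542 genes changed. It recovered 67% of genes changed by 1 on the log2 scale and 17% of those changed by 0.5, with 10 false calls among 94. The data had 5785 calls, and the p-value that passes adjustment depends on how many genes change. These rates therefore do not give the recovery in the data. In 20 simulations of the list test with the autophagy list shifted by 0.5, the shifted list was called in 20 and 1 of 640 unshifted lists was called. The noise was drawn for each gene independently, whereas the correlation estimated within a list reached 0.971 in the data (cytosolic ribosomal proteins). The simulations therefore do not show how often correlated lists are called falsely. Matched random lists, bootstrap intervals and permutations were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib.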

Results

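The data comprised gene-level signal for 17912 genes in 8 total RNA libraries of NKM-1 cells, 4 treated with DMSO and 4 treated with SF153, a compound that the series describes as an inhibitor of splicing factors with a U2AF homology motif (UHM). The series asks how the compound acts on leukemia cells and names cell cycle progression and lysosome acidification as the processes concerned. Each treatment had 2 libraries in each of 2 batches. The genes with a signal of at least 1 numbered between 15080 and 15217 in the DMSO libraries and between 15346 and 15445 in the SF153 libraries. The read depth is unknown. The libraries of each treatment differed in composition. Mitochondrially encoded genes took 16.8% of the signal in both SF153 libraries of batch 2 and between 9.17% and 9.92% in the other libraries. The small nuclear RNA RN7SK took 18.7% and 18.2% in the SF153 libraries of batch 1 and between 11.4% and 13.9% in the others. The first principal component held 50.9% of the variance and separated the treatments.

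Cells treated with SF153 had lower mRNA for DNA replication and mitosis, for ribosomal proteins and for nuclear-encoded respiratory chain subunits, and higher mRNA for cholesterol and fatty acid synthesis, by camera with a preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.0728 for G1/S, 0.137 for G2/M, 0.325 for ribosomal proteins, 0.262 for the respiratory chain, 0.262 for cholesterol and 0.238 for fatty acids). The replication clamp PCNA fell from a signal of 100.2 ± 13.5 to 17.6 ± 3.81 (mean ± SD, n = 4 per group), and the ribosomal protein mRNA RPL7 from 1375 ± 127 to 296 ± 123. The cholesterol synthesis enzyme LSS rose from 55.6 ± 6.47 to 187.3 ± 16.9, and the integrin alpha chain ITGAX from 35.0 ± 1.40 to 142.7 ± 8.57. Of 15542 genes tested, 5785 were called by limma, 2015 higher and 3770 lower in SF153. A change of at least 2-fold was seen in 243 of the higher and 1209 of the lower genes. With the libraries of each treatment and batch averaged, 3517 genes were called. The split between higher and lower calls depended on the scaling between libraries. It was 2015 to 3770 with the authors' values (34.8% higher), 2644 to 3252 after median-of-ratios scaling (44.8%), 3225 to 2822 after quantile normalization (53.3%) and 5826 to 1973 when mitochondrial and small RNA genes were removed before rescaling (74.7%). These scalings moved the median log2 difference of all genes by 0.08, 0.16 and 0.35, so that falls smaller than these shifts have no fixed direction. The medians of the UHM and autophagy lists turned above 0 under each of the 3 other scalings, and those of the glycolysis, iron, p53, stem cell and myeloid lists after quantile normalization as well as without mitochondrial and small RNA genes.

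The largest increases among called genes were those of OLMALINC, a long noncoding RNA gene on chromosome 10 (100373513 to 100454043), and CACNA1E, which encodes a voltage-gated calcium channel subunit. OLMALINC rose from 5.11 ± 0.89 to 41.9 ± 2.80 (log2 difference 2.82 ± 0.12 SE, limma adjusted p = 2.5e-06), and CACNA1E from 2.24 ± 0.53 to 21.2 ± 0.89 (2.79 ± 0.14, limma adjusted p = 4.37e-06). The beta2 integrin partners ITGAD and ITGAX, neighbours on chromosome 16 at 31393312 to 31426505 and 31355134 to 31382997, rose by log2 differences of 2.52 ± 0.21 and 2.0 ± 0.07. The extracellular matrix protein gene SPON2 rose by 2.38 ± 0.12, the sterol carrier gene STARD4 by 2.09 ± 0.10, the tetraspanin-like TM4SF19 by 1.94 ± 0.30 and the RNA-binding protein gene CELF6 by 1.89 ± 0.11. IFI44L, an interferon-stimulated gene, rose by 2.13 ± 0.44, with a log2 difference of 1.05 in batch 1 and 3.22 in batch 2. Its DMSO signal differed between the batches, at 11.54 and 16.24 in batch 1 and 2.79 and 3.6 in batch 2. In SF153 it was 29.28 and 29.48 in batch 1 and 36.95 and 38.78 in batch 2. The pseudogene HMGN2P28 was called higher at 2.16 ± 0.52. It belongs to a family with many near-identical copies, and the call did not pass when libraries were averaged by treatment and batch.

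The largest decreases included PCLAF, the PCNA-associated factor, from 76.0 ± 17.5 to 14.4 ± 10.8 (log2 difference -2.60 ± 0.47 SE, limma adjusted p = 0.00206), and PCNA itself (-2.46 ± 0.15, limma adjusted p = 1.3e-05). The respiratory chain subunits UQCR10 and NDUFC2 fell with log2 differences of -2.49 and -2.43, the calcium-binding protein gene S100A1 with -2.61 and the leukocyte-specific actin-binding protein gene LSP1 with -2.43. RNASE2CP, which the files class as a long noncoding RNA, and the ribosomal protein pseudogene RPS2P5 had log2 differences of -2.88 ± 0.27 and -2.46 ± 0.31. Both carry pseudogene symbols and may share reads with related genes, so their values are uncertain. The top of the ranking held a pair of genes with near-identical copies. The histone gene H3C15 was listed at 0 in each of the SF153 libraries and at 54.5 to 976.8 in DMSO, but its copy H3C14 was listed at 0 in both DMSO libraries of batch 2 and at 241.1 to 343.9 in SF153. Summed over both copies, the signal was 1043.3 ± 102.7 in DMSO and 291.3 ± 54.3 in SF153 (SD, n = 4). BOLA2, also listed at 0 in SF153, and its paralog BOLA2B together had 40.1 ± 10.4 in DMSO and 11.4 ± 6.8 in SF153.

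**Figure D1:**
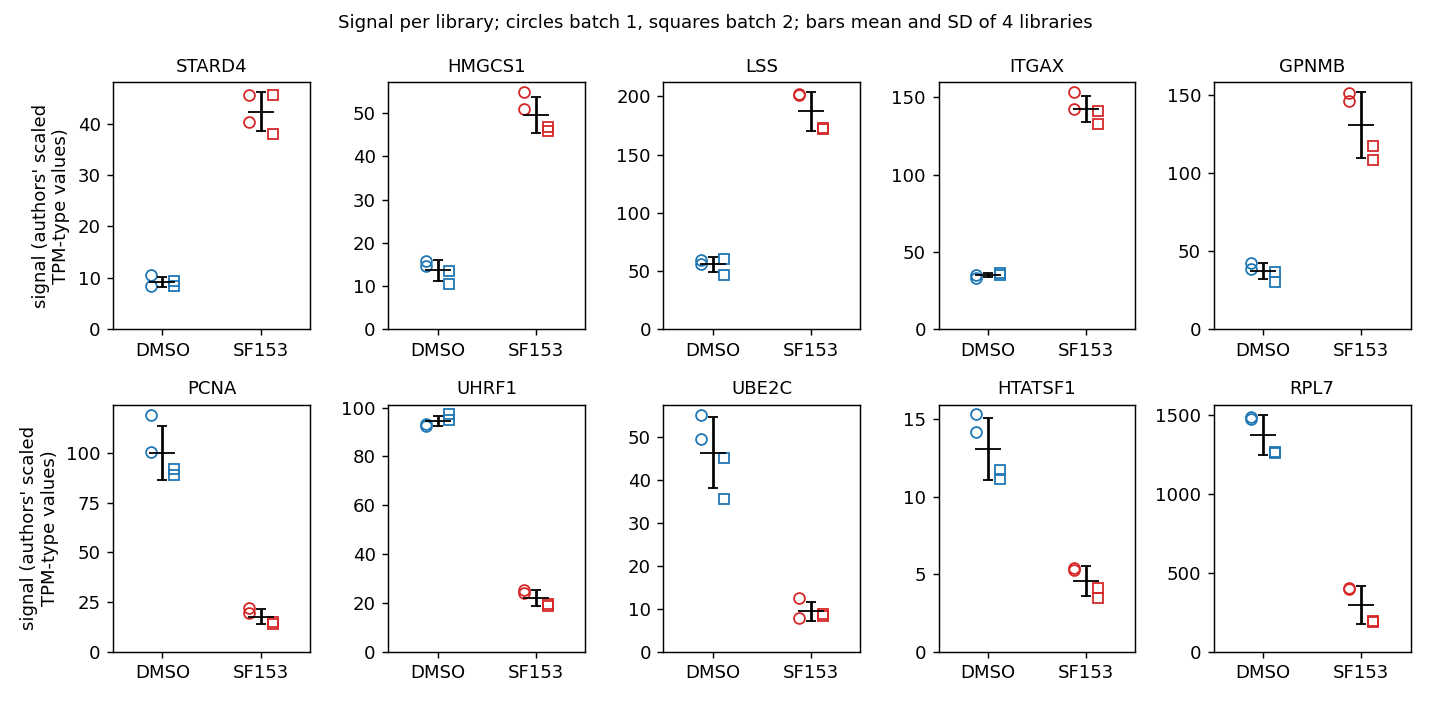
Signal of 10 named genes in each library, on linear axes that start at 0, with open circles for batch 1, open squares for batch 2 and black bars for the mean and SD of 4 libraries. STARD4, HMGCS1, LSS, ITGAX and GPNMB lay higher in every SF153 library than in any DMSO library, and PCNA, UHRF1, UBE2C, HTATSF1 and RPL7 lay lower.

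Cell cycle genes were examined because the series names cell cycle progression. Of 50 genes of G1 and S phase, 48 fell and 0 rose. UHRF1, which maintains DNA methylation at replication, fell from 94.5 ± 2.05 to 21.9 ± 3.32 (log2 difference -2.07 ± 0.10 SE, limma adjusted p = 4.37e-06), the flap endonuclease FEN1 from 29.4 ± 0.88 to 6.91 ± 2.03, and the replication licensing factor CDT1 from 23.3 ± 0.66 to 5.70 ± 1.38. The list had a median log2 difference of -0.94 (camera adjusted p = 3.78e-17; adjusted p = 0.0728 with an estimated correlation). Of 59 genes of G2 and mitosis, 45 fell and 1 rose, with a median of -0.69 (camera adjusted p = 3.57e-13; adjusted p = 0.137 with an estimated correlation). CKS2 and CKS1B, subunits of cyclin-dependent kinases, fell with log2 differences of -2.34 and -2.06, the mitotic ubiquitin-conjugating enzyme UBE2C with -2.19 and the securin PTTG1 with -1.78. Adjusted over the list alone, 48 G1/S genes and 50 G2/M genes were lower, and without mitochondrial and small RNA genes 30 and 28 were lower over all genes. Replication-dependent histone genes, which are transcribed in S phase, fell in 53 of 55 cases and rose in 0, with a median of -1.43 (camera adjusted p = 3.29e-22; adjusted p = 0.254 with an estimated correlation). H4C3, H4C1, H2BC10 and H4C4 had log2 differences of -2.39, -2.34, -2.15 and -2.12. Histone transcripts are near-identical between copies, so single members are uncertain, and the list was no longer called after the trend on length and mean signal was removed (median -0.10, camera adjusted p = 0.0614). Of 12 CDK inhibitors and G1 cyclins and their partners, 6 fell and 1 rose, with a median of -0.32 (camera adjusted p = 0.0351; adjusted p = 0.254 with an estimated correlation). This call was lost in several alternatives. There were 3 higher and 3 lower without mitochondrial and small RNA genes (median 0.05, camera adjusted p = 0.161). It also did not pass after quantile normalization (0.127), averaging by treatment and batch (0.0598), trend removal (median -0.19, 0.248), a mean signal of 5 or more (0.137) or in either batch alone (0.0975 and 0.07). CDKN2C, an inhibitor of CDK4, fell from 99.2 ± 7.12 to 37.1 ± 4.90, CDK4 from 65.6 ± 5.15 to 33.5 ± 2.54 and cyclin D3 (CCND3) from 65.1 ± 4.50 to 38.0 ± 4.58.

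Splicing factors with a UHM are those against which the compound is directed, according to the series title. The list examined also holds their ligands. Of the 12 genes of this list, 5 fell and 1 rose. Camera did not call the list (median -0.06, camera adjusted p = 0.463), whereas fry called it lower (fry adjusted p = 0.000927). These counts hold for the authors' scaling. Without mitochondrial and small RNA genes 6 rose and 1 fell, with a median of 0.32, and after quantile normalization 4 rose and 2 fell. HTATSF1, a U2 snRNP-associated splicing factor, fell from 13.1 ± 2.00 to 4.57 ± 0.95 (log2 difference -1.34 ± 0.16 SE, limma adjusted p = 0.0002). U2AF1, PUF60, UHMK1 and RBM17 fell with log2 differences of -0.47, -0.43, -0.39 and -0.27 under the authors' scaling, and RBM39 rose by 0.23 (limma adjusted p = 0.0489), a call lost without any one DMSO library or either SF153 library of batch 2 (0.18 to 0.25). The call of RBM17 was lost without DMSO 1.1, 2.1 or 2.2 or either SF153 library of batch 1 (-0.28 to -0.22), and averaging by treatment and batch ended those of RBM39, RBM17 and UHMK1. Without mitochondrial and small RNA genes U2AF1, PUF60 and UHMK1 were no longer called and RBM17 had a difference of 0.11. U2AF2 had 101.9 ± 7.09 in DMSO and 101.7 ± 7.22 in SF153, SF3B1 had 220.6 ± 3.23 and 240.3 ± 8.13, and SF1 had 325.0 ± 16.7 and 303.3 ± 11.4. ZRSR2, RBM23 and U2AF1L4 had log2 differences of 0.12, -0.02 and 0.33, none past the threshold with the authors' scaling. Without mitochondrial and small RNA genes the genes U2AF2 (log2 difference 0.377, limma adjusted p = 0.00607), RBM23 (0.347, 0.0201), SF1 (0.284, 0.0158), SF3B1 (0.505, 0.000371) and U2AF1L4 (0.687, 0.00379) were called higher. SF3B1, SF1 and U2AF1L4 were also called higher after quantile normalization, and SF3B1 after median-of-ratios scaling (0.204). After trend removal SF3B1, U2AF1L4 and ZRSR2 were called higher, at 0.18, 1.13 and 0.54, and RBM17, U2AF1 and PUF60 were not called.

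Most of the other splicing factor mRNAs tested fell with the authors' scaling. Of 64 core spliceosome genes, 48 fell and 2 rose, with a median log2 difference of -0.59 (camera adjusted p = 3.96e-10; adjusted p = 0.181 with an estimated correlation). The Sm protein mRNAs SNRPD2, SNRPE, SNRPB and SNRPG fell the most, with log2 differences of -2.38, -1.84, -1.8 and -1.74. Of 34 SR proteins and hnRNPs, which bind pre-mRNA and set splice site choice, 23 fell and 0 rose, with a median of -0.41 (camera adjusted p = 9.28e-08; adjusted p = 0.137 with an estimated correlation). HNRNPA1 fell from 869.9 ± 24.6 to 389.4 ± 48.4, and HNRNPA0, HNRNPH2 and SRSF3 had log2 differences of -1.18, -1.15 and -1.12. The fall of HNRNPA1 was no longer called after quantile normalization (-0.11), and the counts of both lists depended on the scaling. Without mitochondrial and small RNA genes the core spliceosome had 30 lower and 10 higher (median -0.23), and the SR and hnRNP list 13 lower and 6 higher (median -0.02); after quantile normalization the latter had 14 lower and 8 higher. Splice junctions and isoforms were not analysed here.

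Lysosomal genes were examined because the series names lysosome acidification. Of 22 subunits of the V-ATPase, the lysosomal proton pump, 8 fell and 3 rose, and without mitochondrial and small RNA genes 5 fell and 8 rose (median 0.06). With the authors' scaling camera did not call the list (median -0.32, camera adjusted p = 0.218), whereas fry called it lower (fry adjusted p = 0.0253). The members with the largest changes fell. ATP6V1F went from 23.8 ± 1.70 to 10.5 ± 3.22, ATP6V0C from 47.6 ± 5.63 to 22.3 ± 5.80 and ATP6V0E1 from 59.4 ± 8.67 to 28.6 ± 6.26, and the associated subunit RNASEK had a log2 difference of -1.06. ATP6V1F and RNASEK were no longer called after trend removal (-0.20 and -0.15), nor RNASEK after averaging by treatment and batch. Of 58 lysosomal hydrolases and membrane proteins, 15 rose and 15 fell (median 0.01, camera adjusted p = 0.241), a balance that depended on the setting. There were 29 higher and 5 lower without mitochondrial and small RNA genes (median 0.37), 23 and 11 after quantile normalization, and 16 and 9 without SF153 2.1. Batch 1 alone had 12 higher and 7 lower (median 0.13), whereas batch 2 alone had 7 higher and 16 lower (median -0.12), and batch as a block gave 16 and 19. After trend removal 24 were higher and 11 lower, and camera with the preset correlation called the list higher (median 0.23, camera adjusted p = 0.0126). Before trend removal the list had an adjusted p = 0.716 with an estimated correlation, which was not run after it. Acid ceramidase (ASAH1) rose from 76.4 ± 4.58 to 167.5 ± 11.7 (log2 difference 1.12 ± 0.08 SE, limma adjusted p = 1.93e-05), whereas the membrane protein LAPTM4A fell from 40.1 ± 6.71 to 12.8 ± 3.45, the palmitoyl-protein thioesterase PPT1 from 47.1 ± 6.98 to 21.4 ± 6.91 and the glycosylasparaginase AGA with a log2 difference of -1.01. The AGA call was lost without DMSO 2.1, SF153 2.1 or SF153 2.2 (-0.93 to -0.81), after averaging and without mitochondrial and small RNA genes. Of 44 autophagy genes, 9 rose and 9 fell (median -0.07, camera adjusted p = 0.754), but 23 rose and 4 fell without mitochondrial and small RNA genes (median 0.31). The folliculin partner FNIP2 and the phosphoinositide-binding WIPI1 rose by 1.30 and 1.12 on the log2 scale, and the ATG8 family members GABARAP and GABARAPL2 fell with log2 differences of -2.42 and -1.05, the latter not called after trend removal (-0.28). A list named for lysosomal calcium and phospholipid efflux holds mostly lipid transport and storage genes, and no lysosomal calcium channel gene. It had 5 of 13 members higher and 0 lower (median 0.31, camera adjusted p = 0.00577, and adjusted p = 0.156 with an estimated correlation). The number of higher members was 3 without DMSO 1.1, SF153 1.2 or SF153 2.1, 2 (with 1 lower) without SF153 2.2, 2 after averaging and 10 without mitochondrial and small RNA genes. The changed members were led by GPNMB, a glycoprotein of lysosomes and melanosomes, from 37.2 ± 5.20 to 131 ± 21.1, and NR1H3, an oxysterol receptor that drives lipid efflux genes, from 10.2 ± 2.60 to 25.5 ± 4.92. They were followed by APOE, an apolipoprotein that takes up effluxed lipid (log2 difference 0.59), and the lipid droplet protein PLIN2 (0.49). The call of APOE was lost without DMSO 1.1 or 2.2 or either SF153 library of batch 2 (0.47 to 0.57), that of PLIN2 without DMSO 2.1 or 2.2 or SF153 1.2, 2.1 or 2.2 (0.39 to 0.50), and both after averaging.

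Sterol and fatty acid synthesis genes rose together. Of 24 genes of the cholesterol list, 18 rose and 2 fell, with a median log2 difference of 0.71 (camera adjusted p = 7.1e-08; adjusted p = 0.262 with an estimated correlation). HMG-CoA synthase (HMGCS1) rose from 13.6 ± 2.37 to 49.6 ± 4.18 (1.8 ± 0.13 SE, limma adjusted p = 2.33e-05), and lanosterol synthase (LSS) rose from 55.6 ± 6.47 to 187.3 ± 16.9. The list median was 0.96 in batch 1 and 0.48 in batch 2. STARD4, which moves cholesterol between membranes, rose from 9.17 ± 1.03 to 42.4 ± 3.77. Of 11 fatty acid synthesis genes, 8 rose and 0 fell, with a median of 0.81 (camera adjusted p = 2.05e-05; adjusted p = 0.238 with an estimated correlation). The desaturases FADS2 and FADS1 rose by 1.57 and 1.33 on the log2 scale, the transcription factor SREBF1 from 91.5 ± 11.5 to 224.4 ± 16.3, and PNPLA3, at a low signal, by 1.15. Both medians stayed above 0 under the authors' scaling and the 3 others.

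Ribosomal protein and respiratory chain mRNAs had the lowest medians of the 33 lists tested. Each of the 78 cytosolic ribosomal protein genes fell, with a median log2 difference of -1.93 (camera adjusted p = 7.27e-26; adjusted p = 0.325 with an estimated correlation), and RPL7, RPL26, RPS23 and RPL39 had log2 differences of -2.31, -2.26, -2.21 and -2.17. The list median was -1.55 in batch 1 and -2.31 in batch 2, whose SF153 libraries were those with 16.8% of their signal in mitochondrial genes. Of 73 nuclear-encoded oxidative phosphorylation genes, 70 fell and 0 rose, with a median of -1.45 (camera adjusted p = 3.45e-21; adjusted p = 0.262 with an estimated correlation). Cytochrome c oxidase subunit COX5A fell from 122.1 ± 15.9 to 24.1 ± 11.9 and the ATP synthase subunit ATP5PB from 115.4 ± 20.9 to 22.6 ± 7.0. Of 40 genes of ribosome biogenesis that MYC drives, 31 fell and 0 rose (median -0.58, camera adjusted p = 7.79e-09; adjusted p = 0.156 with an estimated correlation), among them FBL, NOP10, NME1 and NHP2 with log2 differences of -1.90, -1.64, -1.62 and -1.59. The medians of these 3 lists stayed below 0 under the 3 other scalings, and ribosome biogenesis had 18 lower and 6 higher without mitochondrial and small RNA genes. After trend removal the medians were -1.12, -0.79 and -0.33, and the 3 lists stayed called by camera with the preset correlation. Glycolysis and hypoxia genes went both ways, with 6 higher and 10 lower of 31 (median -0.13, camera adjusted p = 0.472), and without mitochondrial and small RNA genes 14 rose and 7 fell (median 0.25). The glycolytic enzymes PGAM1, ALDOA, GAPDH and ENO1 had log2 differences of -1.96, -1.92, -1.86 and -1.66.

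Mitochondrially encoded mRNAs and small structural RNAs did not share the fall. Of 13 mitochondrial mRNAs, 3 rose and 0 fell over all genes tested, and limma called 0 when adjusted over the list alone (6 of the 13 had an unadjusted p below 0.05). MT-ATP8, MT-ATP6 and MT-ND4L rose with log2 differences of 0.68, 0.64 and 0.51, calls that were lost without any one DMSO library or either SF153 library of batch 2 (0.40 to 0.73) and after averaging by treatment and batch. Without SF153 1.1 or 1.2 the higher mRNAs numbered 7 and 5. The list median was 0.36, with 0.08 in batch 1 and 0.69 in batch 2 (camera adjusted p = 0.00514; adjusted p = 0.546 with an estimated correlation); the call was lost after quantile normalization (camera adjusted p = 0.0981) and in batch 1 alone (0.277). Of 13 structural small RNAs and nuclear RNAs, 5 rose and 1 fell (median 0.34, 0.58 in batch 1 and 0.03 in batch 2; camera adjusted p = 0.0351; adjusted p = 0.401 with an estimated correlation). This call did not pass without SF153 1.1 (camera adjusted p = 0.0874) or without SF153 1.2 (0.136), after quantile normalization (0.0674), after averaging (0.0701) or in batch 2 alone (0.649). The nuclear RNAs NEAT1 and MALAT1 rose from 1011 ± 26.4 to 1928 ± 210.6 and from 14050 ± 575 to 22620 ± 143, and SCARNA7 and SCARNA10, which guide modification of spliceosomal RNAs, rose by 0.59 and 0.40 on the log2 scale. MALAT1 and SCARNA10 were not called after averaging, nor MALAT1 after quantile normalization (0.41).

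Among nuclear protein-coding genes, the change went with transcript length and abundance together. Ribosomal protein, respiratory chain and histone genes were not set apart in these groups. Genes with a mean signal of 100 or more had a median log2 difference of -1.73 at up to 750 nt (56 genes), -1.75 from 750 to 1500 nt (90 genes), -0.56 from 1500 to 2500 nt (135 genes), -0.12 from 2500 to 4000 nt (172 genes) and 0.01 above 4000 nt (301 genes). At a mean signal of 1 to 10 the median was -0.14 at up to 750 nt (71 genes) and -0.07 above 4000 nt (1157 genes). In both batches the short abundant genes lay lower, with medians of -1.41 in batch 1 and -2.05 in batch 2 at up to 750 nt and a signal of 100 or more.

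**Figure D2:**
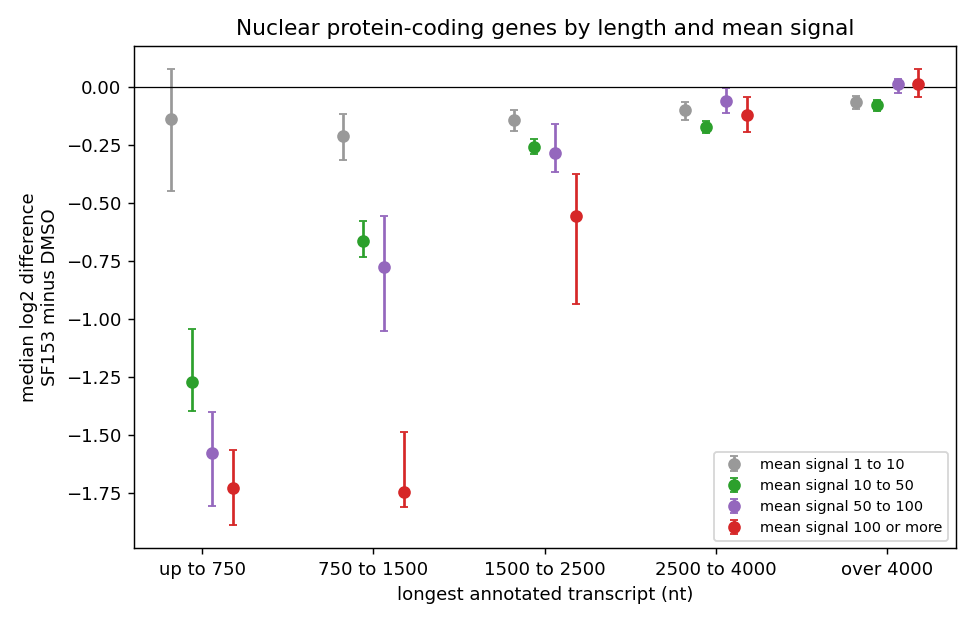
Median log2 difference between SF153 and DMSO (vertical axis) of nuclear protein-coding genes by longest annotated transcript in nt (horizontal axis) and mean signal (colour), with bars for the 95% bootstrap interval over genes. The medians fall to -1.73 for short genes with a signal of 100 or more and stay near 0 for genes above 4000 nt.

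Stress response genes were lower in several lists. Of 19 heat shock genes, 15 fell and 0 rose (median -0.88, camera adjusted p = 2.77e-06; adjusted p = 0.254 with an estimated correlation), with the chaperones HSP90AB1 and HSPE1 falling from 452.3 ± 40.3 to 108.7 ± 40.7 and from 156.0 ± 18.6 to 37.3 ± 13.3, and HSPB1 and DNAJA1 at log2 differences of -1.63 and -1.59. Of 28 unfolded protein response genes, 16 fell and 1 rose (median -0.55, camera adjusted p = 0.000547, and adjusted p = 0.36 with an estimated correlation). Those that fell included XBP1, from 83.4 ± 8.24 to 32.0 ± 13.4, and the disulfide isomerases PDIA6 and PDIA3, at -1.48 and -1.30. After trend removal the median was -0.30 and the list stayed called by camera with the preset correlation. The heat shock list had 2 higher and 12 lower (median -0.51) and the unfolded protein response 5 higher and 11 lower (median -0.23) without mitochondrial and small RNA genes. Of 22 NRF2 targets, 15 fell and 3 rose (median -0.62, camera adjusted p = 0.0073; adjusted p = 0.36 with an estimated correlation), led by the antioxidant enzymes PRDX1 and TXN at -2.03 and -1.86. The NRF2 median lay within the central 95% of lists matched on transcript length and mean signal (-0.653 to -0.03), and the list was no longer called once that trend was removed (median -0.23, camera adjusted p = 0.168). Of the NRF2 targets, 8 fell and 5 rose without mitochondrial and small RNA genes. Of 31 genes of the ATF4 response, 11 fell and 2 rose (median -0.25, camera adjusted p = 0.0337; adjusted p = 0.36 with an estimated correlation), with the serine synthesis enzymes PSAT1 and PHGDH at -1.72 and -1.14 and SLC7A5 and EPRS1 at -1.07 and -1.05. The ATF4 median also lay within its matched range (-0.397 to 0.047) and went to -0.03 after trend removal (camera adjusted p = 0.588). The ATF4 list had 11 higher and 6 lower without mitochondrial and small RNA genes (median 0.11, camera adjusted p = 0.242). The ATF4 call was further lost after quantile normalization (0.203), with a mean signal of 5 or more (0.194), in batch 2 alone (0.0704) and without DMSO 1.2 (0.0516) or SF153 2.2 (0.0502). The p53 targets were not called by camera, with 3 higher and 6 lower of 29 (median -0.14, camera adjusted p = 0.472). Without mitochondrial and small RNA genes they had 11 higher and 3 lower (median 0.23). Their member TNFRSF10B, a death receptor, rose from 41.9 ± 8.83 to 74.0 ± 7.06, and RPS27L, TRIAP1 and PLK2 had log2 differences of -1.81, -1.42 and -1.09. The apoptosis regulators were not called by camera either, with 4 higher and 11 lower of 26 (median -0.37, camera adjusted p = 0.181). Without mitochondrial and small RNA genes they had 7 higher and 5 lower (median -0.01). Survivin (BIRC5) and the BH3 proteins BAD and BID had log2 differences of -0.99, -1.54 and -0.90, and BCL2A1 rose from 1.24 ± 0.47 to 4.83 ± 1.77. Iron genes had 1 higher and 5 lower of 12 (median -0.16, camera adjusted p = 0.458), and 5 higher and 3 lower without mitochondrial and small RNA genes (median 0.18). HMOX1, NCOA4, FTL and FTH1 had log2 differences of -1.32, -1.20, -1.01 and -0.61, and that of FTH1 was 0.10 after quantile normalization. FTL and FTH1 were not called after quantile normalization or trend removal, nor FTH1 after averaging or without mitochondrial and small RNA genes.

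Interferon-stimulated genes were higher, with 19 of 39 rising and 4 falling (median 0.42, camera adjusted p = 2.05e-05; adjusted p = 0.36 with an estimated correlation). MX1 rose from 22.4 ± 9.56 to 62.5 ± 7.80, OAS3 from 10.8 ± 3.51 to 27.5 ± 2.91 and XAF1 from 74.7 ± 11.3 to 159.4 ± 8.71. The list median was 0.16 in batch 1 and 0.70 in batch 2, and 10 members were called higher after averaging. For MX1, OAS3 and XAF1 the DMSO libraries of batch 1 lay above those of batch 2, and the SF153 libraries of batch 1 below. MX1 in DMSO had 32.72 and 28.36 in batch 1 and 13.45 and 15.19 in batch 2. Part of the gap between the batches thus lay in the controls. NF-kB and inflammatory genes were not called by camera, with 2 higher and 4 lower of 18 (median 0.09, mean -0.02, camera adjusted p = 0.655). Without mitochondrial and small RNA genes 9 were higher and 2 lower (median 0.40). SOD2, TNFAIP8 and CCL5 had log2 differences of -0.84, -0.85 and -0.76, and the urokinase gene PLAU rose by 0.83. Of 21 immediate early genes, 9 fell and 1 rose (median -0.27, camera adjusted p = 0.0257; adjusted p = 0.36 with an estimated correlation). Of the 21, 4 rose and 2 fell without mitochondrial and small RNA genes (median 0.09, camera adjusted p = 0.618). The call was also lost after trend removal (median 0.01, 0.646), after quantile normalization (0.271), with a mean signal of 5 or more (0.074) and in batch 1 alone (0.183). MYC fell from 98.5 ± 3.02 to 57.8 ± 11.9 and FOSB from 39.5 ± 2.08 to 18.5 ± 2.17, KLF4 had a log2 difference of -0.53, and KLF6 rose from 49.1 ± 3.05 to 67.4 ± 2.44. Of 6 drug efflux and metabolism genes, 1 rose and 1 fell (median 0.03, camera adjusted p = 0.458), namely ABCC2 at 0.77 and NQO1 at -0.92, whereas 5 rose and 0 fell without mitochondrial and small RNA genes (median 0.39). The ABCC2 call was lost without DMSO 1.1 or 2.2 or SF153 1.1, 2.1 or 2.2 (0.69 to 0.77), and that of NQO1 without DMSO 1.1, 1.2 or 2.1 or SF153 1.1 or 2.2 (-1.03 to -0.74). That of KLF4 was lost without DMSO 1.1, 2.1 or 2.2 or SF153 1.1, 2.1 or 2.2 (-0.54 to -0.46). Averaging ended the calls of ABCC2, NQO1, KLF4 and CCL5, and the scaling without mitochondrial and small RNA genes those of NQO1, KLF4 and CCL5.

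Myeloid differentiation genes went both ways, with 6 higher and 12 lower of 30 (median -0.20, camera adjusted p = 0.463), and 12 higher and 6 lower without mitochondrial and small RNA genes (median 0.14). ITGAX and the sialoadhesin gene SIGLEC1 rose by 2.0 and 1.68 on the log2 scale, whereas the granule protease CTSG fell from 76.9 ± 11.7 to 19.9 ± 7.17. The receptor chain CSF2RA is listed as 2 pseudoautosomal copies that share their sequence. The copy counted as lower in this list had a log2 difference of -1.702 and the other 1.798, and their sum was 8.39 ± 3.83 in DMSO and 9.09 ± 1.51 in SF153, so this call says nothing of the gene as a whole. Of 11 stem and progenitor genes, 5 fell and 1 rose (median -0.17, camera adjusted p = 0.0725), and without mitochondrial and small RNA genes 5 of 12 rose and 3 fell (median 0.22). The receptor FLT3 fell from 129.9 ± 4.33 to 55.1 ± 8.49, and HOXA10, SOX4 and MLLT3 had log2 differences of -0.94, -0.90 and -0.51, that of MLLT3 not called after quantile normalization or without mitochondrial and small RNA genes. Among markers of other cell types, 9 lymphoid genes had 6 lower and 0 higher (median -1.17, camera adjusted p = 0.00466; adjusted p = 0.36 with an estimated correlation), and the 7 with a length were not called after trend removal (median -0.48, camera adjusted p = 0.104). CD2, CD79A, IGHM and JCHAIN had a mean signal between 5.44 and 27.1 in DMSO and log2 differences of -2.17, -2.0, -1.58 and -1.52. Only 1 erythroid or megakaryocyte gene (EPOR, log2 difference -0.00) and 4 epithelial or stromal genes reached the filter, too few for a list test. ACTA2, VIM and PECAM1 had log2 differences of -0.71, -0.48 and 0.61. The call of ACTA2 was lost without DMSO 1.1 or 2.2 or either SF153 library of batch 2 (-0.67 to -0.56), that of VIM without DMSO 1.1, 1.2 or 2.2 or either SF153 library of batch 2 (-0.49 to -0.36), and that of PECAM1 without DMSO 1.1, 1.2 or 2.1 or SF153 1.1 or 2.1 (0.50 to 0.62). ACTA2 and VIM were also not called after averaging, trend removal or without mitochondrial and small RNA genes.

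**Figure D3:**
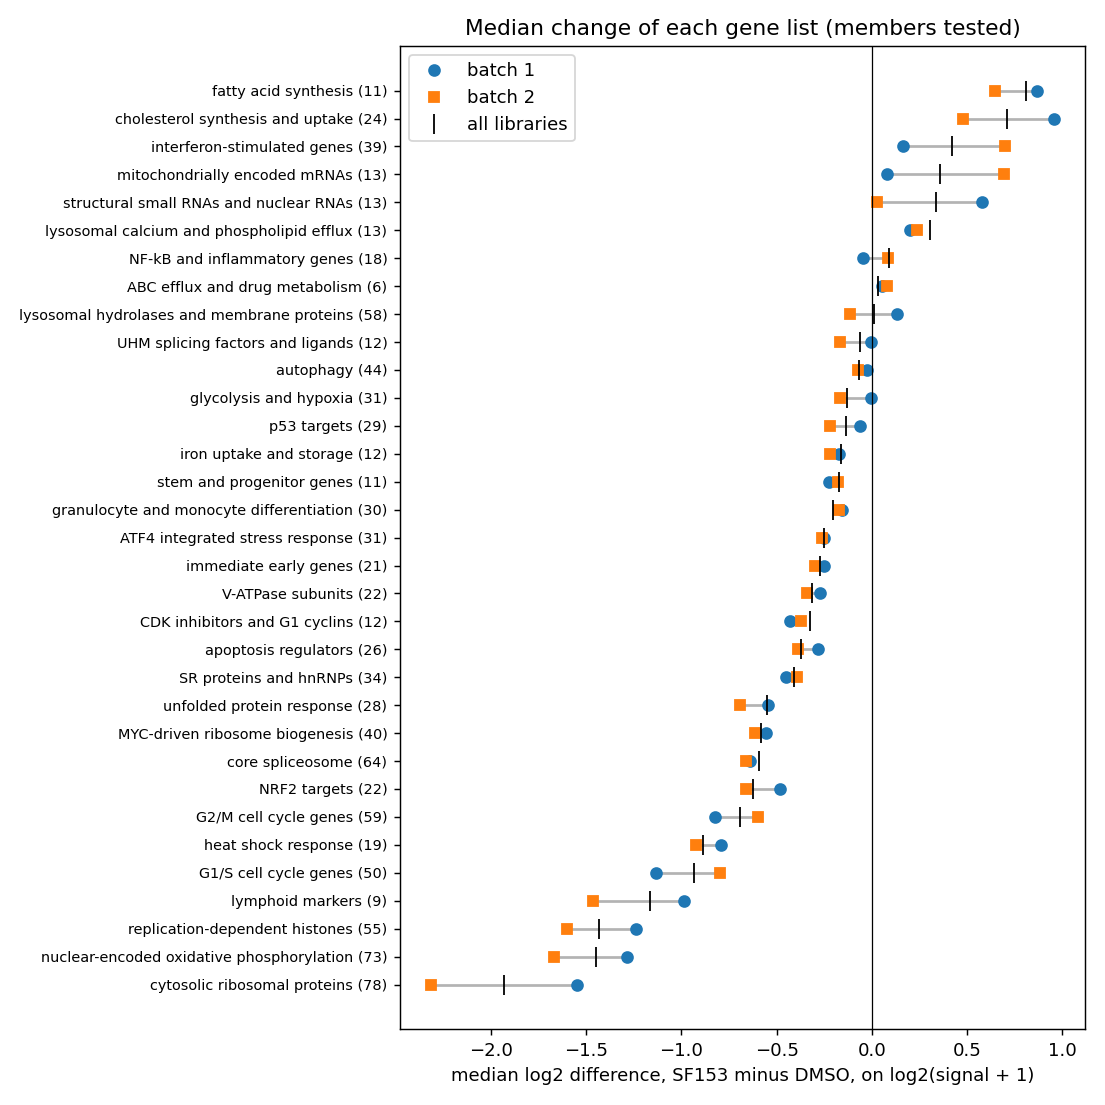
Median log2 difference between SF153 and DMSO (horizontal axis) of each list with at least 5 tested members (vertical axis, number of members in parentheses), in batch 1 (circles), batch 2 (squares) and all libraries (ticks). Cytosolic ribosomal proteins lie lowest at -1.93 and fatty acid synthesis highest at 0.81.

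The difference between SF153 and DMSO was also compared between the batches. Across the 15542 genes, the log2 differences of batch 1 and batch 2 had a Pearson r of 0.682 and a Spearman rho of 0.698, and 77.5% of genes had the same sign. These are values across genes, which are not independent replicates. Within batch 1, limma called 3131 genes, 861 higher and 2270 lower, and within batch 2 it called 3315, 859 higher and 2456 lower. Both batches called 2141 genes with the same sign. An interaction of treatment and batch was called for 178 genes, 155 of them with a lower SF153 minus DMSO difference in batch 2.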

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

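The tests of loss of short RNA, of a lower share of cytoplasmic mRNA and of a uniform scaling shift, the fits to single batches and the removal of the length trend were chosen only after the result was seen. Of the 35 ways to split the 8 libraries into 4 and 4, 1 split, the real one, called as many as 5785 genes. The highest of the others called 3. The other splits mix the treatments, which widens the spread within their groups and by itself lowers their counts. They also ignore the batches. The splits therefore do not exclude chance, even if the libraries are separate cultures. If the 2 libraries of a treatment and batch came from 1 culture, 2 cultures per treatment allow too few splits to judge chance. For the lists, 1 of 35 splits called as many as 21, again the real one, but the highest other split called 20, so the number of lists alone separates the treatments from other splits only narrowly.

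Short abundant mRNAs were lower in SF153, with a median log2 difference of -1.93 for the 78 ribosomal protein genes, and remained lower under the 3 other scalings (-1.85, -1.19 and -1.55). The ribosomal protein genes fell beyond random lists matched on transcript length and mean signal (median -1.014, central 95% -1.268 to -0.712). So did oxidative phosphorylation genes, at -1.45 against -0.562 (-0.82 to -0.336). Matched lists do not reflect correlation within these 2 lists. A general loss of short RNA from the libraries is argued against by mitochondrial mRNAs and small noncoding RNAs with a mean signal of 50 or more. Their median was 0.336 (37 genes, 95% bootstrap interval over genes 0.218 to 0.514), an interval that does not measure the spread between libraries. The median of the mitochondrial mRNAs was 0.081 in batch 1 and 0.693 in batch 2. A lower share of cytoplasmic mRNA in general was examined with 902 genes above 4000 nt with a signal of 50 or more. Their median was 0.012 (-0.015 to 0.041). This test cannot exclude a lower share, because the zero point depends on the scaling and long noncoding RNAs lay 0.242 above genes over 4000 nt. An equal fall of all mRNAs would still not set the ribosomal protein mRNAs, at -1.93, apart from these long ones. A move of reads to pseudogene copies is argued against by the summed signal of 226 ribosomal protein pseudogenes, which changed by -0.07% of the loss of the ribosomal protein genes. An effect of the compound on short, abundant mRNAs remains a hypothesis; differences in RNA recovery or RNA quality that spare mitochondrial and small noncoding RNA were not tested.

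Cell cycle genes were lower in SF153, and part of that fall goes with the trend on length and abundance. Among 10000 random lists matched to the G1/S list on transcript length and mean signal the median was -0.181 (central 95%, -0.352 to -0.021) against -0.94 for the list, and after the trend was removed the list stayed at -0.73 (camera adjusted p = 2.42e-14). For G2/M the matched median was -0.17 against -0.69, and -0.51 after removal (camera adjusted p = 4.1e-10). The medians of these 2 lists thus fell beyond the trend. The calls after removal used the preset correlation, and an estimated one was not run after it. Before removal the estimated correlation gave adjusted p = 0.0728 and 0.137. The matched lists do not reflect correlation among cell cycle genes. A lower share of cycling cells is a candidate explanation that expression data alone do not separate from lower transcription per cell. For the histones, the matched range around -1.714 (-1.875 to -1.282) covers the -1.47 of the 51 members with a length, so their fall did not go beyond the trend. The matched lists could draw ribosomal protein and respiratory chain genes, which fell themselves. Length and abundance were thus not separated from gene class, and whether they account for the histone fall stays open.

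Splicing factor mRNAs were lower in SF153. Lists matched to the core spliceosome had a median of -0.251 (-0.421 to -0.092) against -0.59, and the list stayed at -0.35 after trend removal (camera adjusted p = 2e-05). Lists matched to SR proteins and hnRNPs had a median of -0.117 (-0.352 to 0.094), and the list, at -0.41, lay at their percentile 0.97, between the bounds set beforehand, which alone would leave the trend undecided for this list. After trend removal it stayed called at -0.18 (camera adjusted p = 0.0011), and the rule that counts this against the trend was added after the percentile was seen. By these tests the trend may account for part of the fall but not for all of it. The calls after removal used the preset correlation, and an estimated one was not run after it. Whether this follows from the inhibition of UHM factors was not tested.

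The SF153 minus DMSO difference of 178 genes differed between the batches by the limma interaction test. The same test with camera called 13 lists, whose correlation was preset, so that these calls may be too many given that no list call held with an estimated correlation in the main comparison (0 lists). The median in batch 2 minus that in batch 1 was -0.765 for cytosolic ribosomal proteins, -0.383 for oxidative phosphorylation, -0.359 for histones, -0.48 for lymphoid markers, -0.479 for cholesterol genes, -0.249 for lysosomal hydrolases and membrane proteins, -0.147 for the unfolded protein response and -0.13 for heat shock genes. It was 0.335 for G1/S, 0.223 for G2/M, 0.538 for interferon-stimulated genes and 0.612 for mitochondrial mRNAs, and -0.548 for structural small RNAs.

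In 8 of 324 groups of 4 libraries examined, 1 library lay far from the others. This number cannot be set against chance. Most groups were of genes chosen because they were called, and a batch difference splits the 4 libraries into pairs. DMSO 1.2 had a signal of 34.21 for FADS2 and 53.61 for KLF6, SF153 1.2 had 71.03 for KLF6 and 2.55 for S100A1, and SF153 2.2 had 38.96 for SPON2. DMSO 1.1 had 13.29 for IGHM and 1.19 for HMGN2P28, which was listed at 0 in the other DMSO libraries, and DMSO 2.2 had 4519.28 for MT-ATP6.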

How the results depend on the processing

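The single-batch fits, trend removal, the treatment and batch random effect and the list tests on averages, within batches and after median-of-ratios scaling were chosen after seeing the data. The 5785 calls became 5943 with batch as a block, 5675 of them shared, and the pairing changed no other call of a named gene or list. Removal of mitochondrial and small RNA genes before rescaling gave 5826 higher and 1973 lower genes, and quantile normalization 3225 higher; both move the zero point of all genes. Averaging the libraries of a treatment and batch gave 3517 calls, 948 higher, with fewer samples, and ended 21 of the calls among 154 named genes, those of HMGN2P28, RBM39, RBM17, UHMK1, CDKN2D, RNASEK, AGA, FTH1, CCL5, KLF4, MT-ATP8, MT-ATP6, MT-ND4L, ACTA2, VIM, APOE, PLIN2, MALAT1, SCARNA10, NQO1 and ABCC2. It is the fit to read if libraries of 1 treatment and batch are technical repeats. Trend removal gave 2399 lower genes among 11044 tested and 9 lower lists. The 6 lower lists whose call it ended were the histones, CDK inhibitors and G1 cyclins, ATF4, NRF2, immediate early genes and lymphoid markers, whose medians moved towards 0. Oxidative phosphorylation (-1.45 to -0.79) and the unfolded protein response (-0.55 to -0.30) stayed called at smaller medians, by camera with the preset correlation. Batch 1 alone gave 3131 calls (861 higher, 2270 lower) and batch 2 alone 3315 (859 and 2456), each with 4 libraries. With each library left out in turn, calls ranged from 4872 to 5371 (1555 to 1792 higher, 3293 to 3614 lower), higher lists from 5 to 6 and lower lists from 14 to 15, against 6 and 15. With an estimated correlation, 0 lists were called higher and 0 lower, where 1 and 5 had an unadjusted p below 0.05; camera with the preset correlation called 6 and 15, and fry 5 and 23. Fry placed the NF-kB list, of median 0.091, on the lower side (fry adjusted p = 0.0186), and which members drive this was not tested. Fry, but not camera, also called lower the UHM (fry adjusted p = 0.000927), V-ATPase (0.0253), iron (0.0113) and p53 (0.0012) lists. The same held for the apoptosis (0.000196), glycolysis (0.016) and stem cell (0.00017) lists. The mitochondrial mRNAs were not called by fry (0.123). Fry was run only with the authors' scaling, on which several of these medians depend. The r between batches was 0.793 at a mean signal of 5 or more, 0.509 with a pseudocount of 0.1 and 0.659 after quantile normalization, against 0.682; the cause was not tested. Reversals among named genes were, without mitochondrial and small RNA genes, U2AF2 at 0.377, RBM23 at 0.347, RBM17 at 0.113 and SF1 at 0.284; after quantile normalization, SF1 at 0.658 and FTH1 at 0.1; and after trend removal, U2AF1 at 0.023, FTL at 0.006 and FTH1 at 0.146. The call of BOLA2 was lost without DMSO 2.1 or 2.2 (-2.93 to -2.90), and that of CDKN2D, a CDK inhibitor with a log2 difference of -0.64, without DMSO 1.1, 1.2 or 2.1 or SF153 1.1, 2.1 or 2.2 (-0.68 to -0.50). Pseudocounts, the absence of a filter and variance models left the call and direction of 148 to 154 named genes as they were. Unknown depth limits what can be said of genes listed at 0.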

Other observations

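The test of a uniform scaling shift was chosen only after the result was seen. Noncoding and pseudogene RNAs moved the other way from short mRNAs. Of 2709 long noncoding RNA genes tested, 446 rose and 100 fell, with a median log2 difference of 0.19 in all libraries, 0.20 in batch 1 and 0.18 in batch 2. Of 739 processed pseudogenes, 126 rose and 40 fell (median 0.31), and of 253 transcribed unprocessed pseudogenes, 96 rose and 8 fell (median 0.33). Of 11085 protein-coding genes, 1214 rose and 3599 fell (median -0.15).

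A hypothesis was that these RNAs rise because unspliced host transcripts accumulate when splicing factors are inhibited. Processed pseudogenes that lie sense within a gene body would then rise more than intergenic ones. Only protein-coding genes were taken as hosts, so intergenic means outside these genes. The median of the 421 sense pseudogenes was 0.324 and that of the 273 intergenic ones 0.304. The difference was 0.02 (95% bootstrap interval -0.032 to 0.114, permutation p = 0.508, two-sided, 100000 resamples). The 402 hosts tested had a median of -0.038. The sense and intergenic comparison gave no evidence for the hypothesis, and its interval does not exclude a small excess. The 38 pseudogenes antisense to a gene had a lower median, 0.068, the side that the hypothesis would predict. Sense and antisense pseudogenes were not compared by a test, so the hypothesis stays open. A uniform scaling shift would move long mRNAs as much as long noncoding RNAs, but the noncoding RNAs lay 0.242 above genes over 4000 nt (0.217 to 0.262), so a shift of all genes alone does not account for the difference. Intron signal was not analysed here.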
